A study of Homo sapiens with 3 samples.

How the data were processed

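The data were bulk poly-A RNA sequencing of spinal neurons derived from the human embryonic stem cell line H9, an established line, grown in 3D silk scaffolds. There were 3 libraries, with 1 library per group: a dorsal monoculture, a ventral monoculture and a coculture of dorsal and ventral neurons. RNA was taken 4 weeks after seeding. All scaffolds received 1 µM cAMP and 10 ng/mL each of the growth factors BDNF, GDNF and NGF, and moved to a Neurobasal-based medium on maturation day 7. The proportion in which dorsal and ventral cells were seeded together is not given in the sources used here.

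The authors deposited 3 gene tables, each with 1 column per library. Their processing notes name the aligner HISAT2 with no version, featureCounts 2.0.6, edgeR 4.0.16 and genome build hg38. Annotation version, strand setting, handling of multi-mapping reads and any filter are not given in the sources used here, and the library description does not settle whether strand was kept. The deposited count table held whole-number raw counts for 58735 genes, of which 31108 had a count in any library. All 58735 gene identifiers are in GENCODE release 29, and 58724 have the same start and end there. The deposited FPKM table was checked against the counts: each column was the count divided by the gene length in the file and by a constant for the library, 40855057 for dorsal, 46680549 for ventral and 34326838 for the coculture. The deposited table of z scores held a score per gene and library that followed a straight line in log2 FPKM within each library, with minus infinity at 0 counts. A score of 0 stood for a log2 FPKM of 2.66 in the dorsal, 2.68 in the ventral and 2.35 in the coculture library, and a unit of the score for 1.78, 1.79 and 2.05. The score was therefore not a comparison across libraries and was not used further.

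All comparisons started from the counts. Effective library sizes came from the trimmed mean of M values (TMM) over the 3 libraries, with edgeR 4.0.16 in R 4.3.3. Log2 ratios used CPM, the counts scaled to the effective library size, with a prior count of 2, and 16063 genes with a mean CPM of at least 1 were kept. With n = 1 per group no dispersion can be estimated, so no test between groups was made and no p-value is given. Each ratio has a 95% exact conditional (Clopper-Pearson) interval that covers counting error only. Genes were called by size: a ratio of at least 4-fold with an interval excluding equality, or at least 2-fold for members of gene lists and for genes outside the range of both monocultures. A library at 0 counts was set to a floor of 3 counts per library, and the fold given as at least a value is then a bound on reads taken as independent. Molecule-adjusted bounds are lower. Those 3 counts are 0.074 CPM in the dorsal, 0.064 CPM in the ventral and 0.089 CPM in the coculture library.

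For 45 gene lists, the median log2 ratio of the kept members was set against 10000 random lists of the same size, drawn with seed 11 from the 50 genes on either side of each member in mean expression. The percentile describes these libraries only. Interval bounds of a list's median are order statistics of its members, and with 8 or fewer members they are the lowest and highest member. The position of the coculture was the ventral weight, (coculture - dorsal) / (ventral - dorsal) on linear CPM, for genes at least 4-fold apart between the monocultures. The lists, the size rules, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. The text names members of the lists, the 12 protein-coding genes per direction with the largest conservative fold in each comparison, the 12 per direction outside both monocultures, and the 10 genes with the most counts in each library. Mitochondrially encoded and ribosomal protein genes were left out of the ranked sets. The conservative fold is the interval bound nearest to equality. Lists of further sterol pathway genes, fatty acid synthesis genes and LXR target genes were chosen after the values of the ranked genes had been seen.

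Reads per independent molecule were estimated for each library from genes at 0 counts although the other 2 libraries agreed within 0.5 on the log2 scale and each predicted 20 to 80 reads. The value is an upper estimate, because a gene can also be at 0 for biological reasons. Intervals on counts divided by it, called molecule-adjusted intervals, were added after the data had been seen, as were a minimum mean CPM of 20 over the 3 libraries, over the monocultures or as a geometric mean of monoculture and coculture CPM, TMM over the monocultures alone and the share of genes between a pair with the roles of the libraries exchanged. Alternatives fixed in advance were DESeq2 1.42.0 size factors, library totals alone, upper-quartile factors, no expression filter, a mean CPM of at least 5, prior counts of 0.5 and 5, the authors' FPKM plus 0.1, protein-coding genes alone, removal of mitochondrially encoded and ribosomal protein genes, an interval beyond the fold threshold, gene sets at least 8-fold apart and a log2 scale for the ventral weight. Shares of counted genes have exact (Clopper-Pearson) intervals. Exons shared with other genes were counted in GENCODE release 29 for 442 named genes. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

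The procedure was tested on simulated data with 16063 genes. With independent reads, 100.0% of genes set 8-fold apart and 40.0% of genes set 4-fold apart were called at least 4-fold higher, 0 unchanged genes were called, and the plain intervals held the true ratio for 95.2% of unchanged genes. A mix with a ventral weight of 0.6 returned 0.599 from dorsal-high genes. With 15 reads per molecule, 94.0% of genes set 8-fold apart were called, but 95 unchanged genes were called higher and 108 lower. In the same setting 191 unchanged genes were called above and 348 below both other libraries, against 0 and 0 at a mean CPM of at least 20. The plain intervals then held the true ratio for 38.3% of unchanged genes and the molecule-adjusted intervals for 98.2%, and the estimator returned 19.9 reads per molecule.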

Results

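Gene expression was measured by RNA sequencing in 3 libraries of H9-derived human spinal neurons kept for 4 weeks in silk scaffolds: a dorsal monoculture, a ventral monoculture and a coculture of both (n = 1 each). The effective library sizes were 40453459 counts for the dorsal, 46897549 for the ventral and 33780156 for the coculture library. Protein-coding genes with a count numbered 16316, 15988 and 15582. Counts of list members below are of those that passed the expression filter. MAP2, a dendritic microtubule protein, was at 1211, 1216 and 1258 CPM in the dorsal, ventral and coculture library, and DCX, a microtubule protein of young neurons, at 2708, 2986 and 3118 CPM. Of 14 pan-neuronal genes, 1 was at least 2-fold higher in dorsal than ventral (NEFM, a neurofilament subunit, log2 ratio 1.30, 95% counting interval 1.29 to 1.32), 0 were lower and 13 were neither. NEFM shares 38.9% of its exon bases with an antisense gene. In the coculture 2 were lower than in dorsal (NEFM and NEFH) and 1 was lower than in ventral (NEFH). The tubulin gene TUBB3 had only 142, 194 and 220 counts. In the annotation it shares 35.8% of its exon bases with a gene on the same strand that had 0 counts, so its level is uncertain.

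There was no replicate check, and the intervals cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Among genes for which the other 2 libraries each predicted 20 to 80 reads, 38 of 888 were at 0 counts in the dorsal library (4.28%, exact 95% interval 3.05 to 5.83), 67 of 852 in the ventral (7.86%, 6.15 to 9.88) and 95 of 1035 in the coculture (9.18%, 7.49 to 11.1). Independent reads would leave close to 0 such genes. The upper estimate of reads per independent molecule was 12.2, 15.8 and 16.5, so the plain intervals are likely too narrow. It rests on genes predicted at 20 to 80 reads. Other levels of expression were not assessed, and the plain intervals may be too narrow there as well. The cause of the excess of genes at 0 counts was not tested. A fold given as at least a value sets a library at 0 counts to 3 reads counted as independent, so it is a bound on reads and not on molecules. With counts divided by the reads per molecule, the log2 bound nearest to equality was -7.13 for VSX2 and 6.09 for ZIC2 in dorsal over ventral. Where fewer members of a list were called with these molecule-adjusted intervals, their number follows as adjusted, and where no such number follows it was the same. Mitochondrially encoded genes took 3.51%, 1.85% and 3.69% of the counts and ribosomal protein genes 2.83%, 2.77% and 4.11%. The mitochondrial ribosomal RNA MT-RNR2 alone took 0.511%, 0.372% and 1.22%. The most abundant transcript was MT-CO1 in the dorsal library (338078 counts), TUBA1A in the ventral (226442 counts) and MT-RNR2 in the coculture (445268 counts).

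The comparison of the monocultures asks whether each culture carries the identity of its side of the spinal cord. Several transcription factors of the dorsal neural tube and spinal cord were high in the dorsal library and at few or 0 counts in the ventral library. ZIC1, a dorsal neural tube factor on chromosome 3 (147393422 to 147510293, GRCh38), had 3973 counts against 3 (log2 ratio 9.76, 95% counting interval 9.04 to 12.86). POU4F1, a factor of dorsal interneurons and sensory neurons on chromosome 13 (78598362 to 78603560), had 6658 against 8 (9.55, 8.93 to 11.13), with 27.7% of its exon bases shared with an antisense gene. MSX1, a BMP-induced roof plate factor, had 10757 against 62 (7.60, 7.29 to 8.04). ZIC2 was at least 1330-fold higher, with 3440 counts against 0. Factors of ventral interneurons included genes high in ventral only: VSX2, which marks V2a interneurons, on chromosome 14 (74239472 to 74262738), had 7313 counts in the ventral and 0 in the dorsal library and was at least 2100-fold higher in ventral. SOX14 was at least 1550-fold and LHX3, shared by V2 interneurons and motor neurons, at least 1060-fold higher in ventral. NKX6-1, a ventral progenitor factor, had 5168 counts against 14 (dorsal over ventral -8.12, -9.19 to -7.57).

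Of 12 dorsal progenitor factors 7 passed the filter, and these 7 were at least 2-fold higher in dorsal (6 adjusted), with a median log2 ratio of 7.22 (2.89 to 9.76), and 0 of 10000 random lists reached that median. Among the other members NEUROG1 had 0 counts in dorsal and 15 in ventral, GSX1 0 and 8, and OLIG3 0 and 0. Of 12 dorsal interneuron factors, 9 were higher, among them LHX9 (8.62), TLX3 (777 counts against 0) and LMX1B (7.78), and 3 were lower (1 adjusted): PAX2 (-3.21), FOXP2 (-1.38) and BHLHE22 (-1.11). Their median of 5.39 became 4.99 with genes at 0 counts held at their bound. Of 7 ventral interneuron factors, 4 were lower in dorsal, 1 was higher (EVX1, a V0 factor, 2.51) and 2 were neither. Of 5 ventral progenitor factors, NKX6-1 and NKX6-2 (-7.04) were lower and the other 3, OLIG2, SHH and PRDM12, were neither. OLIG2, the motor neuron progenitor factor, had 49 counts in dorsal and 48 in ventral, and NKX2-2, which marks p3 progenitors, had 0 and 10. Of 12 motor neuron genes, 5 were lower in dorsal (6 under library totals alone), among them MNX1 (0 counts against 595) and LHX4 (-6.87, with 30.8% of its exon bases shared with ACBD6), 1 was higher (ALDH1A2, which makes retinoic acid, 3.16) and 6 were neither. ISL1 was at 85.0 CPM in dorsal and 69.5 CPM in ventral. CHAT, which makes acetylcholine, had a log2 ratio of -0.80.

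Over all kept genes, 867 were at least 4-fold higher in dorsal and 231 in ventral. Under library totals alone, which moved the median log2 ratio of all genes by -0.13, the counts were 798 and 282. Besides the factors above, the genes with the largest conservative folds in dorsal included TFAP2B, a neural crest and sensory factor, with 14336 counts against 6 (10.96, 10.31 to 12.88), POSTN, a matrix protein, with 12905 against 6 (10.81, 10.16 to 12.73), MAL, a myelin and lymphocyte membrane protein (at least 1720-fold), the matrix gene FREM2 (at least 1050-fold) and BMP5, a secreted growth factor (at least 670-fold). IFITM1, at least 498-fold higher, shares 32.5% of its exon bases with its paralog IFITM2, so its counts are uncertain. In ventral they included GBX2, a hindbrain and spinal cord factor, with 6456 counts against 44 (dorsal over ventral -6.92, -7.45 to -6.56), NKX6-3 (-5.73), SP8 (634 counts against 0), the metabolic enzyme gene TKTL1 (-6.02) and ARX, a floor plate and interneuron factor with 181 counts against 0.

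**Figure D1:**
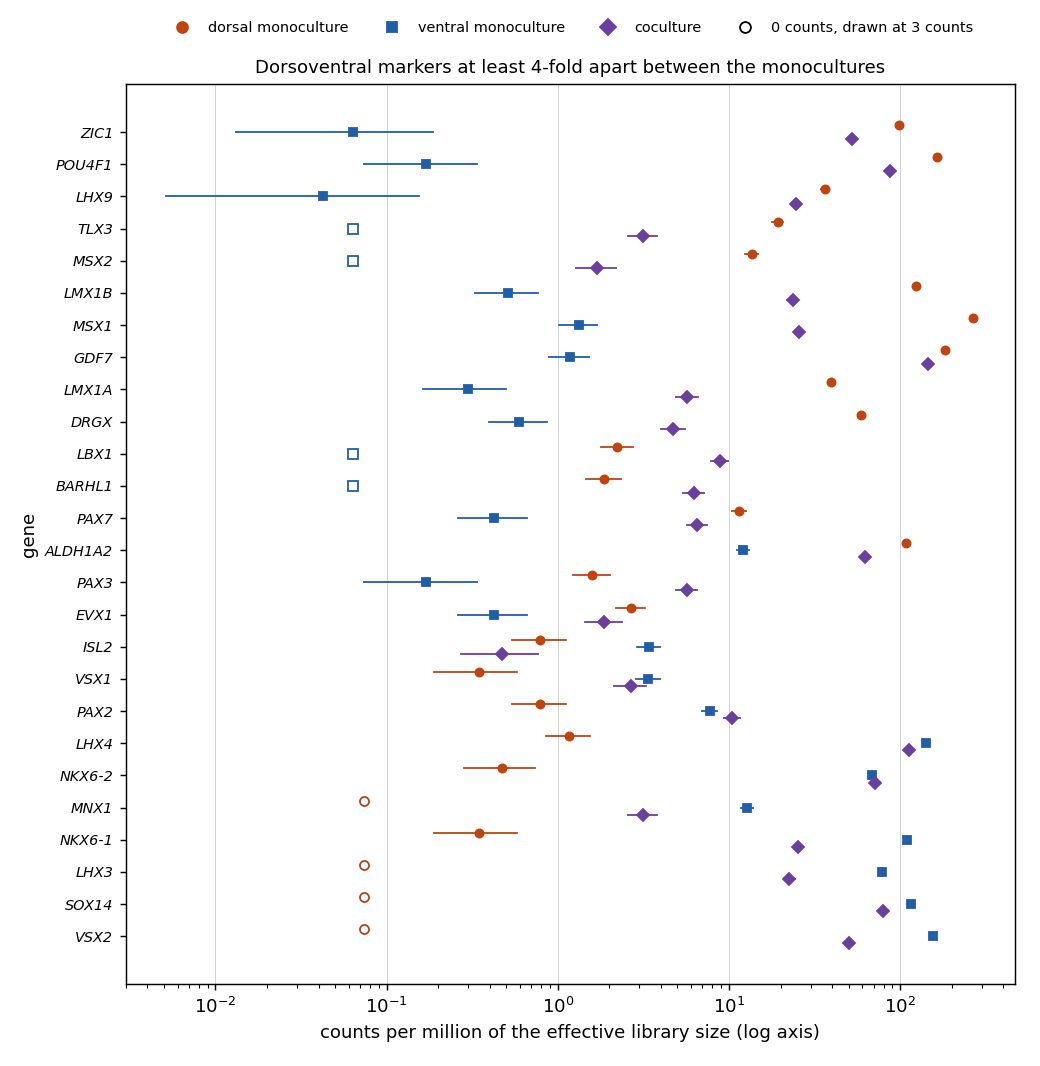
Expression of dorsoventral marker genes at least 4-fold apart between the monocultures, as CPM on a log axis, in the dorsal monoculture (circles), ventral monoculture (squares) and coculture (diamonds), 1 library each. Lines are exact 95% Poisson intervals, open symbols stand for 0 counts and are drawn at 3 counts, and ZIC1 runs from 98.2 CPM in dorsal to 0.064 CPM in ventral with the coculture at 52.6 CPM.

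Target genes of BMP signalling, which patterns the dorsal cord, were higher in dorsal for 9 of 10 members, with SMAD7 neither (median log2 ratio 4.04, 2.19 to 7.60). ID3, an inhibitor of bHLH factors, had a ratio of 5.73 (5.53 to 5.96) and ID1 of 4.43 (4.26 to 4.64). Of 6 roof plate genes, 4 were higher, including LMX1A (6.84) and RSPO3 (1460 counts against 0), and 2 were neither (median 7.03). Of 5 floor plate genes, 4 were lower and SHH was neither (median -2.99), with NTN1, an axon guidance cue, at -2.99 (-3.18 to -2.83) and SULF1 at -3.05. Of 4 WNT targets, 3 were higher (2 under library totals alone and with upper-quartile factors), with LEF1 at 316 counts against 0 and AXIN2 at 1.06. Of 4 retinoic acid targets, 2 were higher, 1 was lower (STRA6, -1.06) and 1 was neither. Of 7 Notch pathway genes, 2 were higher (HES1, 3.12, and HEY1, 1.71), HES5 was lower (-1.19, 0 lower adjusted) and 4 were neither. Both Hedgehog targets that passed the filter, PTCH1 (-0.02) and PTCH2 (0.59), were neither.

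HOX genes, which set position along the head-to-tail axis, differed by paralog group. Of 10 genes of paralog groups 5 to 9, 9 were higher in dorsal (8 under library totals alone) and HOXB5 was neither, with a median of 1.37 (1.08 to 3.20). HOXB9 (1.70, 1.65 to 1.75) and HOXB8 (1.57, 1.53 to 1.61) had 358.9 and 459.6 CPM in dorsal. Of 12 genes of groups 1 to 4, 2 were lower (HOXB1, -3.16, and HOXA4, -1.47, and 3 under library totals alone and with upper-quartile factors), HOXD1 was higher (1.57) and 9 were neither (median -0.55). HOXD1, HOXD3, HOXD4 and HOXC5 share over 50% of their exon bases with other genes and are uncertain. HOXA4 shares 47.3% with a gene on the same strand. Of 12 genes of groups 10 to 13, 0 passed the expression filter, and of 12 forebrain and midbrain factors only EN2 did, with 97 counts in each monoculture. Of 4 serotonergic and hindbrain motor factors, PHOX2A (2.39) and PHOX2B (1.75) were higher in dorsal, and TBX20 (-5.05) and TPH2 (-3.02), the serotonin-synthesis enzyme, were lower (1 adjusted).

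The vesicular glutamate transporter SLC17A6 was at 251.1 CPM in dorsal and 257.5 CPM in ventral. Of 15 glutamate genes, 6 were higher in dorsal, including the vesicular transporters SLC17A8 (4.28) and SLC17A7 (2.32), GRIK3 (2.31) and GRIN1 (2.15), GRIK2 was lower (-1.37) and 8 were neither. Of 5 inhibitory transmitter genes, 3 were lower in dorsal: GAD1, which makes GABA (-1.87, -2.36 to -1.48), the glycine transporter SLC6A5 (-2.02) and the vesicular transporter SLC32A1 (-1.45). The GABA transporter SLC6A1 was higher (5.39). Of 12 GABA and glycine receptor genes, 3 were higher, including GABRA5 (3.70), 2 were lower and 7 were neither (2 higher and 1 lower adjusted, and 2 higher and 3 lower under library totals alone). Of 10 dorsal horn neuropeptides, 5 were lower in dorsal (4 adjusted), among them NTS (neurotensin, 1416 counts against 16602, -3.34), CALCB (-3.50) and SST (somatostatin, 1220 counts against 8021), PENK (enkephalin) was higher (2.26, 2.16 to 2.38) and 4 were neither. Of 10 peptide, opioid and cannabinoid receptors, 6 were higher (5 adjusted), such as NPY1R (5.75) and SSTR1 (4.58), 1 was lower (the kappa opioid receptor OPRK1, -4.24) and 3 were neither.

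Of 11 sensory neuron genes, 6 were higher in dorsal (4 adjusted, 4 under library totals alone and 5 with upper-quartile factors) and 5 were neither, with PIEZO2, the mechanosensitive channel, at 10487 counts against 108 (6.78, 6.54 to 7.10) and SCN9A, a sodium channel of pain neurons, at 1.55. PRPH (1.14) shares 56.2% of its exon bases with an antisense gene. Of 8 neural crest and Schwann genes, 3 were higher (TFAP2A, TFAP2B and SNAI2), MPZ was lower (-1.23, and 2 were lower under library totals alone and with upper-quartile factors) and 4 were neither. Of 8 neurotrophin and GDNF receptors, 4 were higher (3 adjusted and 3 under library totals alone), including GFRA2 (2.78) and NTRK2 (2.17), GFRA1 was lower (-1.09) and 3 were neither. Of 26 synaptic genes, 25 were neither and CPLX2 was lower in dorsal (-1.12). Of 15 voltage-gated channel genes, KCNA1 (24.1 CPM in dorsal and 0 counts in ventral) and KCNQ3 (2.04) were higher and 13 were neither. Of 24 axon guidance genes, 6 were higher (5 under library totals alone and with upper-quartile factors), led by EFNB3 (3.67, 3.62 to 3.71) and UNC5C (2.94), 4 were lower, among them SLIT3 (-2.52), and 14 were neither.

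Of 11 astrocyte genes 7 passed the filter, and these 7 were higher in dorsal (6 adjusted, median 2.33, 1.38 to 9.11), with S100B at 1237 counts against 2 (8.38, 7.63 to 12.53) and the glutamate transporter SLC1A3 at 4.57, while GFAP, below the filter, had 4 counts in dorsal and 12 in ventral. Of 16 proliferation genes, 9 were higher, including MKI67 (4.87, 4.55 to 5.32) and TOP2A (4.20), 1 was lower (TYMS, -1.14, with 46.6% of its exon bases shared) and 6 were neither. Of 10 neural progenitor genes, 5 were higher, such as SOX2 (4.87), 2 were lower (1 adjusted and 3 under library totals alone) and 3 were neither. Of 11 fibroblast and matrix genes, 8 were higher, including COL1A2 (36751 counts against 105, 8.63) and COL3A1 (754 counts against 0), 2 were lower, with COL1A1 at -2.09 (-2.28 to -1.92) and ACTA2 at -1.74, and 1 was neither. ACTA2 shares 30.1% of its exon bases with an antisense gene. Of 6 cartilage genes 5 were higher, with COL2A1 at 5.08, and of 4 choroid plexus and ependymal genes 3 were higher, with FOXJ1 at 2.85. Of 5 oligodendrocyte genes, PDGFRA was higher (128 counts against 0), MBP was lower (-1.18) and 3 were neither. Of 4 skeletal muscle genes 2 were higher, including the dorsal factor PAX7, and 1 was lower (1 higher and 0 lower adjusted). Of 6 epithelial genes 3 were higher (2 with DESeq2 size factors, library totals alone or upper-quartile factors), with KRT19 at 3.01, and of 4 endothelial genes 2 were higher, with KDR at 3.70. Of 3 pluripotency genes LIN28A was lower in dorsal (-3.28) and 2 were neither, and POU5F1 had 6 counts in dorsal and 0 in ventral. Of 8 microglial genes, 0 passed the expression filter.

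Of 11 hypoxia response genes, P4HA1 was higher in dorsal (2.17) and 10 were neither. Of 10 ER stress and amino acid response genes, 4 were lower in dorsal (5 under library totals alone), with SESN2 at -1.32 (-1.38 to -1.26) and CHAC1 at -1.08, and 6 were neither. Their median was -0.74 (-1.17 to 0.02), and 0 of 10000 random lists were as low. Of 10 immediate early genes, 3 were higher: EGR2 (4.53), EGR1 (1.62) and NPAS4 (1.47). Of 10 cholesterol synthesis genes, INSIG1 was higher (1.03, 0.95 to 1.11, and under 2-fold under library totals alone and upper-quartile factors) and 9 were neither.

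**Figure D2:**
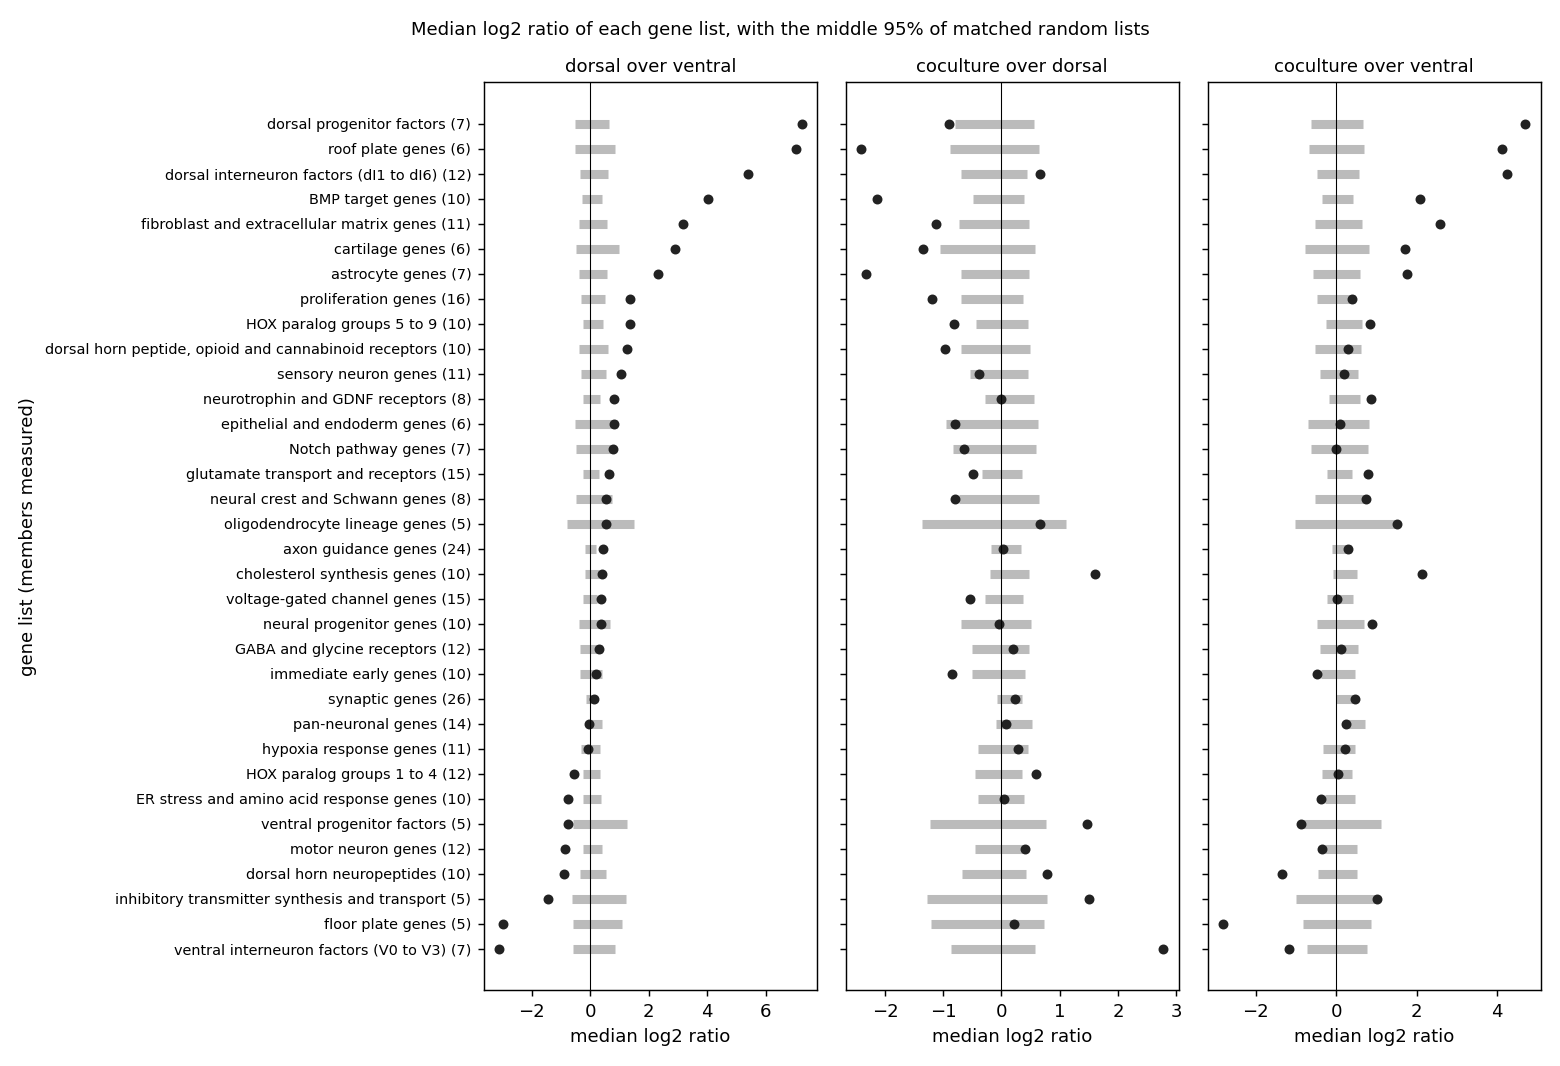
Median log2 ratio of each gene list with at least 5 members past the expression filter (points) in the 3 pairs of libraries, n = 1 per group, with the middle 95% of 10000 expression-matched random lists as grey bars. Dorsal progenitor factors stand at 7.22 for dorsal over ventral and cholesterol synthesis genes at 1.60 and 2.12 for the coculture over the dorsal and the ventral library.

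The coculture was compared with each monoculture to ask what the combined culture holds of both sides and where it departs from them. Against the dorsal library, several factors of the ventral side were gained. SOX14 was at least 1070-fold, VSX2 at least 679-fold and LHX3 at least 304-fold higher, with 2682, 1701 and 761 counts against 0. NKX6-2 had a log2 ratio of 7.11 (6.60 to 7.99), LHX4 of 6.54 (6.18 to 7.04) and GBX2 of 6.17 (5.80 to 6.70). MNX1, the motor neuron factor, had 106 counts against 0, with a molecule-adjusted log2 bound of 1.06. Of 5 ventral progenitor factors 3 were higher (2 adjusted) and 2 were lower (0 adjusted). Of 7 ventral interneuron factors 4 were higher (3 adjusted), 1 was lower (GATA2, -2.17, 0 lower adjusted) and 2 were neither. Of 5 inhibitory transmitter genes 3 were higher, with SLC6A5 at 3.02 (2.66 to 3.50) and GAD1 at 3.00 (2.63 to 3.49), and SLC6A1 and SLC6A9 were lower. Somatostatin (SST) was at 171.0 CPM against 30.2 CPM in dorsal.

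Other genes were lower in the coculture than in dorsal, though many stayed above ventral. All 10 BMP targets were lower (median -2.13, -3.09 to -1.25), among them ID2 (-3.09) and ID3 (-2.33). Against ventral 8 of these 10 were higher (6 adjusted), 0 lower and 2 neither. Of the 10, 0 were outside both monocultures (1 below both under library totals alone). For 36 dorsal-high genes with ventral counts at most 1% of dorsal and dorsal CPM at least 20, the median over dorsal was -2.04. These genes, MSX1 among them, were chosen for few ventral counts, so they are no matched reference for the BMP targets. Of 10000 expression-matched random lists 0 were as low as the BMP targets, but those lists were not matched on dorsal over ventral. Whether the fall was particular to BMP targets was therefore not decided. Of 16 proliferation genes 10 were lower, with MKI67 at -2.51 (-2.72 to -2.32), and 6 were neither (8 lower adjusted, 12 under library totals alone and 9 with upper-quartile factors). Against ventral 5 of the 16 were higher (3 adjusted) and 3 were lower (5 under library totals alone). Of 7 astrocyte genes 4 were lower, with SLC1A3 at -4.60 (-4.90 to -4.35), while FGFR3, a growth factor receptor, was higher (2.04, 1.91 to 2.18). Against ventral 4 of these 7 were higher and 1 was lower (0 lower adjusted). Of 11 fibroblast and matrix genes 6 were lower (5 adjusted), with POSTN at -4.29 (-4.42 to -4.17). Against ventral 8 of the 11 were higher and 2 were lower (5 higher and 1 lower adjusted). Of 15 voltage-gated channel genes 5 were lower (6 under library totals alone), among them SCN3A (-1.47) and CACNA1C (-1.48), KCNC1 was higher (1.07, and under 2-fold under library totals alone) and 9 were neither. Between the monocultures 13 of these 15 were neither. Against ventral 2 of the 15 were higher and 0 were lower (2 lower under library totals alone). PENK was lower by -4.76 (-5.08 to -4.49) and TFAP2B by -3.82 (-3.92 to -3.72). Over all kept genes 291 were at least 4-fold higher and 665 lower. Among the lower genes, the largest conservative folds were for genes at or near 0 in the coculture. GPNMB, a membrane glycoprotein, was at least 220-fold lower and NPAS4, an activity-induced factor, at least 156-fold. ASPM, a spindle protein, was at least 138-fold and SOST, a WNT inhibitor, at least 102-fold lower.

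Against the ventral library, dorsal factors were gained. ZIC1 had 1776 counts against 3 (8.86, 8.13 to 11.96), POU4F1 2943 against 8 (8.63, 8.02 to 10.21) and LHX9 830 against 2 (8.06, 7.31 to 12.22). ZIC2 was at least 621-fold and BMP5 at least 425-fold higher. The 7 dorsal progenitor factors past the filter were higher (6 adjusted), with a median of 4.70 (3.79 to 8.86), or 3.07 with the authors' FPKM plus 0.1. Of 12 dorsal interneuron factors 10 were higher and 2 were neither. COL1A2 had 14055 counts against 105 (7.51, 7.26 to 7.83), and OTP, a factor of neuropeptide neurons, 2428 against 17 (7.45, 6.95 to 8.41). The 5 floor plate genes past the filter were lower, with SULF1 at -2.82 (-3.02 to -2.65) and ARX at 0 counts against 181 (molecule-adjusted log2 bound -0.86). Of 7 ventral interneuron factors 4 were lower (2 adjusted), with VSX2 at -1.63 (-1.71 to -1.55), EVX1 was higher (0 adjusted) and 2 were neither. Of 10 dorsal horn neuropeptides 6 were lower (4 adjusted), with NTS at -1.96 (-2.02 to -1.91), TRH was higher (2.49) and 3 were neither. Over all kept genes 562 were at least 4-fold higher and 401 lower. Library totals alone moved the median of all genes by -0.24 and turned these counts to 438 and 538, so the split of higher and lower genes depends on the scaling. The same scaling moved the median of the coculture over the dorsal library by -0.11.

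The coculture lay between the monocultures for 30.1% of kept genes, and the dorsal and ventral libraries lay between the others for 34.2% and 35.7%, where unordered libraries would give 33.3% each. Among genes at least 4-fold apart between the monocultures, the coculture lay between for 720 of 867 dorsal-high genes (83.0%) and 149 of 231 ventral-high genes (64.5%). Choosing genes far apart in a pair itself favours a place between for the remaining library, so 33.3% is no reference for these shares. With the roles exchanged, the ventral library lay between for 68.0% of genes at least 4-fold higher in the coculture than in dorsal and 51.4% of those lower. The dorsal library did for 38.3% of genes higher in the coculture than in ventral and 62.8% of those lower. For the same chosen genes the median ventral weight was 0.715 (95% interval 0.682 to 0.741, quartiles 0.463 and 0.889) from dorsal-high genes and 0.507 (0.369 to 0.599, quartiles 0.166 and 1.00) from ventral-high genes. These intervals treat genes of the same libraries as independent, so they do not measure how the position would vary between cultures. On a log2 scale, which by construction moves a place between the monocultures toward the higher one, the order of the sets turned, to 0.408 and 0.732. Dorsal-high genes stood at different levels of the dorsal library in the coculture. The factors LBX1, PAX3 and BARHL1 were above the dorsal level, at 398%, 357% and 335%. These percentages rest on few dorsal counts, given below, and are imprecise. GDF7, a roof plate signal, was at 79.4%, LHX9 at 67.8%, ZIC1 at 53.6% and POU4F1 at 52.9%, but LMX1B at 19.1%, MSX1 at 9.61%, TFAP2B at 7.08% and the matrix gene POSTN at 5.11%.

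At least 2-fold outside both monocultures were 536 genes above and 897 below, 74 of the latter at 0 counts in the coculture. With the dorsal library in this role the counts were 955 and 472, and with the ventral library 334 and 1012. Library totals alone moved the share above from 37.4% to 23.4%, with 361 above and 1182 below. At a mean CPM of at least 20 there were 122 above and 100 below, and at a mean CPM of at least 50 there were 74 above and 19 below. This mean includes the coculture, so genes above both pass it more easily. At a mean CPM of at least 20 in the monocultures, which genes below both pass more easily, there were 92 above and 137 below. Molecule-adjusted intervals gave 317 above and 321 below.

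**Figure D3:**
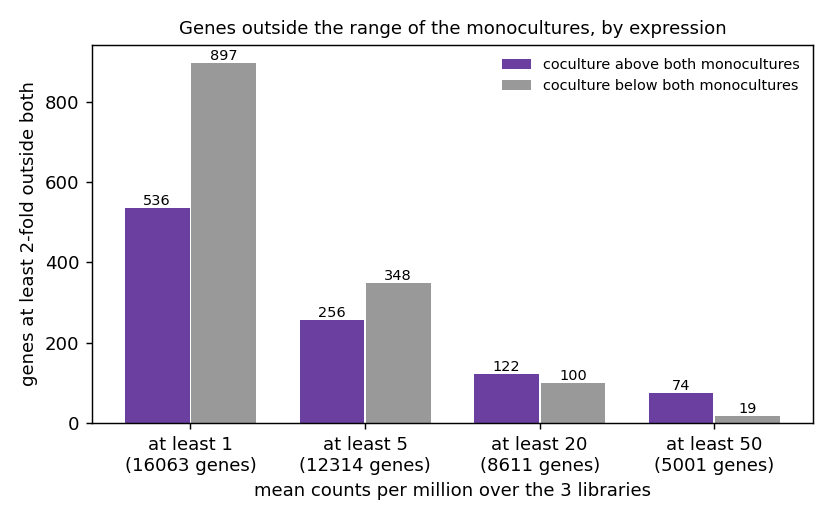
Number of genes at least 2-fold above or below both monocultures in the coculture, n = 1 library per group, by the minimum mean CPM over the 3 libraries. Genes below outnumber genes above at a minimum of 1 (897 against 536), and genes above outnumber genes below at a minimum of 50 (74 against 19).

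Genes of cholesterol synthesis and uptake rose above both monocultures together. All 10 members of the list were at least 2-fold higher than in each monoculture, with a median log2 ratio of 1.60 (1.21 to 2.17) over dorsal and 2.12 (1.62 to 2.61) over ventral, and 0 of 10000 random lists reached either median. HMGCR, the rate-limiting enzyme, on chromosome 5, was at 1042 CPM against 367.3 in dorsal and 230.5 in ventral (log2 ratio to ventral 2.18, 2.15 to 2.21). DHCR7, the last step of the pathway, on chromosome 11 (71428193 to 71452868), was higher by 2.33 (2.27 to 2.39) and 2.61 (2.55 to 2.67), and LDLR, the receptor for low-density lipoprotein, by 2.17 (2.12 to 2.23) and 2.56. SC5D, with the smallest ratio to dorsal at 1.05 (0.99 to 1.11), fell under 2-fold with library totals alone, which left 9 members. SCD, which desaturates fatty acids, on chromosome 10 (100347124 to 100364834), and STARD4, a sterol carrier, ranked among the 12 genes furthest above both, with SCD at 2.22 (2.20 to 2.24) and 2.79 (2.77 to 2.82). FDPS, HMGCS1 and IDI1 share 18.6%, 15.0% and 14.8% of their exon bases with other genes.

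**Figure D4:**
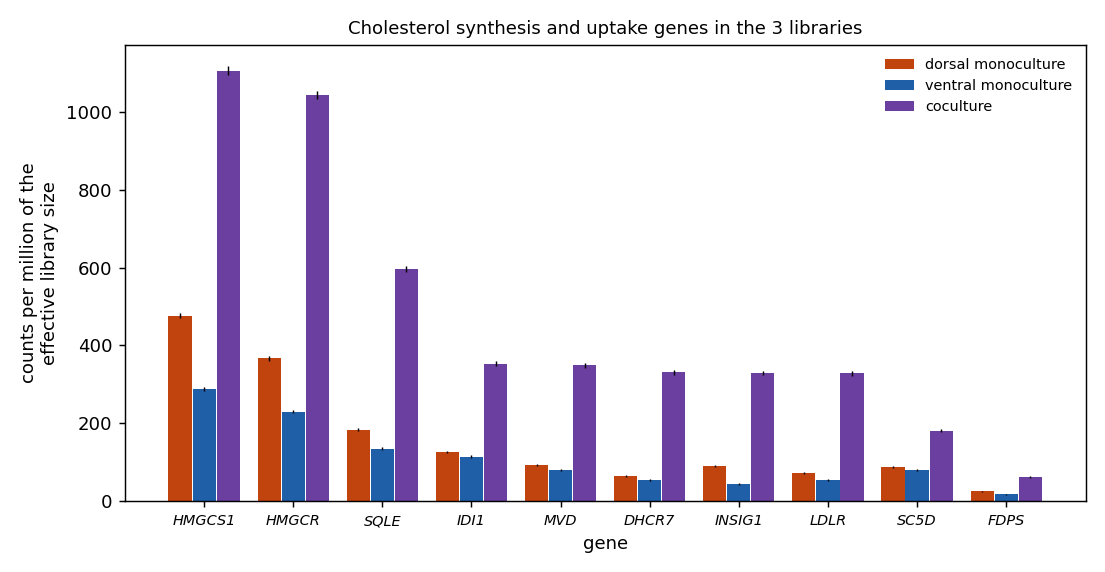
Expression of the 10 cholesterol synthesis and uptake genes as CPM in the dorsal monoculture, ventral monoculture and coculture, 1 library each, with exact 95% Poisson intervals as error bars. HMGCR is at 367.3, 230.5 and 1042 CPM and DHCR7 at 66.1, 54.4 and 331.6 CPM, and every gene is at its highest in the coculture.

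Other genes above both monocultures included DLK1, a Notch-related membrane protein, with 4540 counts against 366 and 372 (3.89, 3.74 to 4.05, and 4.07, 3.93 to 4.24), HRH2, a histamine receptor, with 515 against 68 and 29, and PRIMA1, which anchors acetylcholinesterase, with 528 against 80 and 62. MME, a peptidase, had 134 counts against 2 and 0, and ARHGAP8 (203 against 24 and 9) shares 32.6% of its exon bases with a readthrough gene. Members of the dorsal interneuron and dorsal progenitor lists were also among them: LBX1 (299 counts against 90 and 0), BARHL1 (210 against 75 and 0), LHX1 (539 against 283 and 86), BHLHE22 (340 against 50 and 128) and PAX3 (191 against 64 and 8). Of these, BHLHE22 was higher in the ventral than in the dorsal library. GAD1 and SLC6A5 were above both (373 counts against 54 and 235, and 392 against 56 and 270), but library totals alone left neither at least 2-fold above ventral, and DESeq2 size factors left 1 of these 2 above both. VAMP2, a synaptic vesicle protein, was the 1 of 26 synaptic genes above both (1.30 and 1.31).

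Below both monocultures were 4 of 10 immediate early genes, which respond to neuronal activity: FOSB (4 counts against 993 and 846), NPAS4 (0 against 560 and 233), EGR1 (239 against 1808 and 679) and JUNB (373 against 946 and 1111). With upper-quartile factors 3 of them were. The other 6 were not below both, and FOS was at 58.4 CPM against 89.8 and 75.9, and ARC at 15.5 CPM against 15.3 and 13.9. GPNMB had 0 counts against 790 and 893 and was at least 214-fold lower than in ventral. The serotonin receptor gene HTR2A (117 and 124 counts in the monocultures), the gene of the myeloid surface protein CD14 (154 and 122) and that of the midbrain factor EN2 (97 in each) were at 0 counts in the coculture. Their molecule-adjusted log2 bounds against ventral were -0.20, -0.17 and 0.26, so EN2 was not separated from equality. NEFH, the heavy neurofilament subunit, was the 1 of 14 pan-neuronal genes below both (463 counts against 1983 and 2957), and TAC1 and PENK the 2 of 10 neuropeptides.

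Ratios from the deposited FPKM ranked the genes almost as the counts did: across genes, which are not independent replicates, Spearman's rho was 0.999 for dorsal over ventral, 0.999 for coculture over dorsal and 0.998 for coculture over ventral.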

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

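The molecule-adjusted intervals, every filter at a CPM of at least 20 and TMM over the monocultures alone were chosen after the data had been seen. Counts are given in the order dorsal above ventral, ventral above dorsal, coculture above and below dorsal, above and below ventral, and above and below both, for which the main values are 867, 231, 291, 665, 562, 401, 536 and 897.

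With no expression filter they were 3379, 2776, 2639, 3750, 3047, 3723, 2790 and 2247, because genes with few counts then enter. The ventral weights were 0.962 and 0.0 against 0.715 and 0.507, the share of genes with the coculture between was 21.88% against 30.06%, and the pluripotency median over dorsal was 0.03 against 0.80. With a mean CPM of at least 5 the counts were 463, 93, 119, 221, 263, 72, 256 and 348, and with at least 20 they were 210, 50, 57, 61, 120, 20, 122 and 100, as fewer genes were tested. The share between was 28.23% with the latter. A mean CPM of at least 20 in the monocultures left 92 above and 137 below both, and a geometric mean of monoculture and coculture CPM of at least 20 left 123 and 68. Where the interval had to lie beyond the fold threshold, 144 genes were above dorsal in ventral, 172 and 431 above and below dorsal and 239 below ventral in the coculture, and 300 and 507 above and below both, a stricter rule by construction. Molecule-adjusted intervals, wider by construction, left 195 below ventral, 317 above both and 321 below both. With protein-coding genes only, a smaller set, 246 were below ventral and 585 below both.

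With library totals alone the median of HOX paralog groups 1 to 4 over ventral was -0.21 against 0.03. That of pluripotency genes was -0.57 against -0.34. Both moved much as the median of all genes over ventral did, by -0.24. The log2 scale gave ventral weights of 0.408 and 0.732, since by construction it moves a place between the monocultures toward the higher one. For the following the cause was not tested. With library totals alone the ventral weights were 0.757 and 0.365 and the share between was 30.78%. With the authors' FPKM, 369 genes were above ventral in the coculture and the median of dorsal progenitor factors over ventral was 3.07 against 4.70. Gene sets at least 8-fold apart gave a weight of 0.743 from dorsal-high genes.

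Of the alternative values, 70 counts of genes stayed within 1.5 times their main value and 40 did not, 1327 list medians stayed within the interval of the median and 4 did not, and 12113 ratios of named genes stayed within their counting interval and 1200 did not. For a list of 8 or fewer members that interval spans all members, so its median could hardly leave it. The largest move of a list median without a change of filter was 2.27 on the log2 scale. No list median that was at least 1 in size on the log2 scale was reversed. Neither was any named-gene ratio of that size whose counting interval excluded equality. Without a change of filter, 16 values of list medians changed sign, each with a main value under 1 in size. With 1 library per group no library could be left out, and depth limits the genes with few counts. For reads taken as independent, a gene at 0 counts can be as high as 0.074 CPM in dorsal, 0.064 in ventral and 0.089 in the coculture. With up to 12.2, 15.8 and 16.5 reads per molecule in these libraries, the true limits can be several times higher.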

Other observations

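The lists of further sterol pathway genes, fatty acid synthesis genes and LXR target genes, and the tests of sparse sampling for genes below both monocultures, were chosen after the results had been seen.

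Of 13 further sterol pathway genes 8 were at least 2-fold above both monocultures and 0 below, among them FDFT1, the first committed step to sterols (25817 counts against 7501 in dorsal and 7772 in ventral), DHCR24 (1.48, 1.45 to 1.52 over dorsal, and 1.76, 1.73 to 1.80 over ventral) and MSMO1 (1.41 and 2.10). CYP51A1, with 83.2% of its exon bases shared with a gene on the same strand, and TM7SF2, at -0.47 and -0.06, were not. Of 8 fatty acid synthesis genes 3 were above both, namely SCD, FASN (48960 counts against 28558 and 24968) and FADS2 (1.72 and 1.51), and FASN was under 2-fold over dorsal with library totals alone. SCD had already been seen among the ranked genes when the list was chosen. Of 6 LXR targets, which respond to sterol excess, 0 were above or below both, with ABCA1 at -0.17 and -0.50.

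The collagen chains COL1A1 and COL1A2, which assemble into the same fibril, differed in opposite directions between the monocultures. COL1A2 stood at 908.5 CPM in dorsal and 2.24 CPM in ventral, and COL1A1 at 7.47 CPM in dorsal and 32.0 CPM in ventral. In the coculture COL1A2 was at 416.1 CPM and COL1A1 at 7.99 CPM. No explanation was tested.

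A first pattern is that all 10 cholesterol synthesis genes were above both monocultures. Sparse sampling of molecules does not account for it, since the lowest molecule-adjusted log2 bound over the members and both monocultures was 0.82, above 0. Scaling does not account for it either, since at least 9 of the 10 members stayed 2-fold above both under library totals alone, upper-quartile factors and DESeq2 size factors. A share of 0.615 of the further sterol genes was above both, as higher sterol-regulated transcription in this coculture would give. That list was chosen after the ranked genes, STARD4 among them, had been seen, so the share is not independent support. With 1 library per condition, a difference in the handling of that culture beyond the stated medium and age stays open and untested, as does an effect of culturing both cell types together.

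A second pattern is that more genes were below than above both monocultures, with a ratio of 1.67. The ratio stayed above 1 under each of 3 other scalings, but ran from 1.37 with upper-quartile factors to 3.27 with library totals alone. These scalings raised the coculture median of all genes by at most 0.09 over dorsal and 0.02 over ventral on the log2 scale. They therefore cannot exclude scaling as a cause. The ratio was 1.01 with molecule-adjusted intervals. At a mean CPM of at least 20 it was 0.82 over the 3 libraries, which genes above both pass more easily. It was 1.49 over the monocultures, which genes below both pass more easily, and 0.553 with a geometric mean of monoculture and coculture CPM. The filter thus decides the outcome. With 15 simulated reads per molecule and no change, 348 genes were below and 191 above both, so sparse sampling alone can put more genes below. At a mean CPM of at least 20 that simulation gave 0 and 0. Sparse sampling of molecules in the coculture library therefore stays open as a cause. No biological explanation was tested.

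The last pattern is the unequal dilution of dorsal-high genes in the coculture. Among 36 such genes with ventral counts of at most 1% of dorsal and a dorsal CPM of at least 20, the median level in the coculture was 24.3% of dorsal, and 63.9% had a molecule-adjusted interval that excluded that median, 14 above and 9 below it. With 1 library per condition the spread between scaffolds is unknown, so a mix in a single proportion cannot be told apart from other compositions by this test. Among 15 of these genes with a dorsal CPM of at least 100 the figure was 80%, which argues against sparse sampling as the whole cause. Variation between scaffolds, the cell composition and gene regulation in the coculture stay open.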
